A study of Mus musculus with 24 samples.

How the data were processed

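The analysis used the deposited scanner output of 24 one-colour arrays and the deposited value table of the authors. Per the file headers the deposited signal intensities were read from the images by Agilent Feature Extraction 12.0.3.1, with spatial and multiplicative detrending and surrogate values for signals near background. Probe positions in the files are on the mouse build NCBI37 (mm9). Each array has 59305 spots without controls, which are 56605 probes. Per the labels each sample was RNA of 10 follicles, and the 3 replicates of a group were 3 independent experiments. The labels name biotin as the label, while the scans hold 1 green channel, and the values were used as signal intensity in either case. Of the probes, 35405 were matched to a symbol by RefSeq accession, which changed 1 symbol.

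The value tested was log2 of the processed signal intensity minus the 75th percentile of it on the same array. A probe was tested if it was well above background on every array of at least 1 group, and 33340 probes passed. Spots that Feature Extraction marked as non-uniform (41) or as an outlier were set to missing, and 25 probes well above background were left out for such a spot. No spot was saturated. The probe with the highest mean stood for a gene or transcript, which left 22065, of which 7693 had more than 1 tested probe. Groups of 3 arrays were too small for a test of outlying arrays, and no array was left out.

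Each group had 1 mean in a limma model with 16 residual degrees of freedom and 2.19 prior degrees of freedom, and the 17 comparisons were contrasts of these means. P-values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05, and they measure the spread between these samples. The sum of single compounds was taken on the log2 scale. An average effect is the mean of the effect over the 4 backgrounds. For gene lists with at least 5 measured members, limma camera was run with a preset correlation of 0.01 and again with an estimated correlation, with fry as another test, adjusted over 39 lists. The lists were written from general knowledge and not from these samples. In the average effects and the comparison of PEE-PH-TA with control, up to 12 genes with the largest rise and 12 with the largest fall are named. Elsewhere 5 of each are named. They had to pass the threshold, with arrays fully separated or, for averages, with the same sign in all 4 backgrounds and all 3 replicate numbers. Gene models, clones and accessions were left out of this choice except where under 3 genes passed. For a list up to 2 risers and 2 fallers past the threshold are named, and Pgf and Flt1 in any case. Some genes chosen in this way are not reported here, and no other took their place. These choices and all alternatives but the 2 named below were made before the data were examined. For average effects, a lower bound replaces the fold where at least 1 of the 4 groups on the lower side was dim on all its arrays, a choice made after the data were seen.

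Alternatives were quantile normalization, normexp background with an offset of 50, the value table of the authors, no filter on dim probes, the mean of all tested probes of a gene, replicate number as a block, limma with a trended and robust prior, only the arrays of the groups compared, and leaving out each array or each replicate number. The log2 75th percentile signal of each array as a covariate, and gene lists without each replicate number, were chosen after the data were seen. Normexp moved the median of all genes to -0.10 with PEE-PH, -0.12 with PH-TA and 0.10 for PEE-PH-TA against PH-TA. Without the filter 36593 genes or transcripts were tested, and the median was 0.12 with PEE, -0.19 with PEE-PH, -0.14 with PEE-TA and -0.20 with PH-TA, and -0.14 for PEE-PH against the sum. For the average effect of PH it was -0.11.

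The value table of the authors holds log2 values whose array medians ran from 3.73 to 3.78 and whose sorted values differed by 0.0440, as after quantile normalization. Its 24 columns each correlated best with their own scan, with slopes of 0.978 to 1.02 on log2 signal. The labels do not state its background step.

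Simulated data with the same groups had 100 genes shifted by log2 0.5 and 100 by log2 1. Of these 49% and 78% were called for PEE-PH-TA against control (6 false calls), 8% and 40% for the sum of all 3 compounds (4 false) and 80% and 97% for the average effect of PEE (5 false), with 0 called in the wrong direction. A simulated shift of the NRF2 list was called, and 0 others of 39 lists, which does not test lists of correlated genes. Tools were R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and Python 3.11.15 with matplotlib 3.10.9. Scanner images, hair length and protein measurements were not used.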

Results

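Vibrissa follicles of 9-day-old mice were kept in culture for 24 h without an added compound or with panthenyl ethyl ether (PEE, 0.3%), pyridoxine hydrochloride (PH, 0.015%), tocopherol acetate (TA, 0.024%) or their combinations. Each of the 8 groups had 3 one-colour Agilent arrays, 24 in all, and each of 3 slides carried 1 array per group. Of 22065 genes or transcripts tested, 15570 had a gene name that is not a model or an accession. Between 58.3 and 62.5% of the spots of an array were well above background, and the 75th percentile of signal ran from 142 (PEE replicate 2) to 248 (PH-TA replicate 1). Arrays of the same group correlated across genes at r = 0.993 to 0.997, where genes are not independent replicates. The number of arrays limited precision. Of genes shifted by log2 0.5 and 1 in simulated data, 49% and 78% passed for PEE-PH-TA against control. For the sum of all 3 compounds 8% and 40% did. There were 17 comparisons, each tested by limma at an adjusted p of 0.05. Values after ± are standard errors unless said otherwise, and fold changes are log2 unless called fold.

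The first principal component held 29.7% of the variance and 89.4% of its own variance lay between groups, against 5.19% between slides. Control arrays scored -24.2 to -41.0 on it, PEE arrays -35.7 to -47.8 and PEE-PH arrays 9.33 to 34.6. PEE-PH-TA arrays scored -4.44 to 6.04. The second component, with 16.5%, parted the cultures with PEE from those without it, and 97.3% of its variance lay between groups. The third held 6.84%, and 60.7% of its variance lay between slides.

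**Figure D1:**
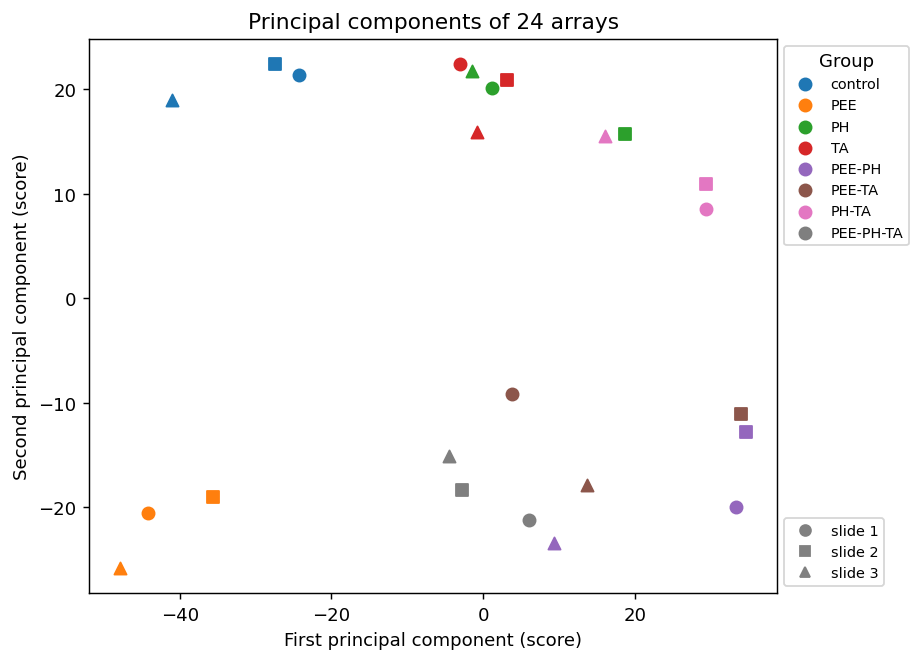
Scores of the 24 arrays on the first 2 principal components of log2 signal, coloured by culture group and shaped by slide. Cultures with PEE lie low and those without it high on the vertical axis.

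Pgf (NM_008827, chromosome 12, 86508335 to 86510337 in mm9), which encodes the placental growth factor, rose with TA, with PEE-PH, with PEE-TA and with PH-TA, while Flt1, which encodes its receptor VEGFR-1, rose with 5 of the 7 treatments. Pgf was 0.61 ± 0.14 higher than control with TA (limma, adjusted p = 0.0372), 0.49 ± 0.14 with PEE-PH (0.0109), 0.52 ± 0.14 with PEE-TA (0.0117) and 0.53 ± 0.14 with PH-TA (0.00919), n = 3 arrays per group. With PEE-PH-TA its value was 0.26 ± 0.14 and did not pass (0.234), nor did 0.05 with PEE (0.861) and 0.27 with PH (0.299). In log2 relative to the 75th percentile of each array, Pgf had a mean ± SD of -0.08 ± 0.04 in control, 0.52 ± 0.09 with TA and 0.18 ± 0.17 with PEE-PH-TA. Averaged over the backgrounds, the effect of TA on Pgf was 0.28 ± 0.07 (adjusted p = 0.0241), that of PH 0.09 (0.336) and that of PEE -0.02 (0.884). The 4 Pgf calls against control rested on single arrays, while 0 of 24 arrays ended that of the average effect of TA (highest adjusted p 0.0484). Without control replicate 3 the adjusted p with TA was 0.146, and each of the 6 arrays left out in turn ended that call. Without PEE-PH replicate 1 it was 0.0584 with PEE-PH, without PEE-TA replicate 2 it was 0.0786 with PEE-TA, and without PH-TA replicate 1 it was 0.06 with PH-TA. Without replicate numbers 1, 2 and 3 the average effect of TA had 0.0742, 0.126 and 0.264, and each of the 4 calls against control ended without at least 2 of the numbers. With array signal as a covariate, chosen after the data were seen, PEE-TA had 0.038 and the other calls ended (0.0774 with TA, 0.122 with PEE-PH, 0.293 with PH-TA and 0.301 for the average effect of TA), and without the filter on dim probes TA had 0.0663. Only 1 probe measured Pgf.

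Flt1 (NM_010228, chromosome 5, 148373791 to 148373850 in mm9) was 0.56 ± 0.15 higher than control with PEE (limma, adjusted p = 0.0198), 0.96 ± 0.15 with PEE-PH (8.38e-05), 0.72 ± 0.15 with PEE-TA (0.00197) and 0.79 ± 0.15 with PH-TA (0.00104). With PEE-PH-TA it was 0.53 ± 0.15 higher (0.019), n = 3 arrays per group. PH alone gave 0.33 (0.208) and TA alone 0.11 (0.772), which did not pass. Its mean ± SD was 0.63 ± 0.10 in control, 1.59 ± 0.13 with PEE-PH and 1.15 ± 0.28 with PEE-PH-TA. The average effect on Flt1 was 0.38 ± 0.07 for PEE (0.000619), 0.30 for PH (0.00478) and 0.07 for TA (0.581). Without control replicate 1 the call with PEE ended (0.077), and 4 of the 6 arrays ended it. Without PEE-PH-TA replicate 3 the call with PEE-PH-TA ended (0.0988), and 3 of the 6 arrays did so. Without replicate number 2 the adjusted p was 0.285 with PEE, 0.12 with PEE-TA and 0.196 with PEE-PH-TA, and 0.077 and 0.0604 for the average effects of PEE and PH, and without number 3 it was 0.0555 with PEE and 0.155 with PEE-PH-TA. With array signal as a covariate it was 0.128 with PEE, 0.132 with PH-TA and 0.262 for the average effect of PH. Of 4 Flt1 probes, 3 were well above background on 24 arrays, with PEE-PH-TA values of 0.53, 0.32 and 0.31, and 1 on 0 arrays.

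**Figure D2:**
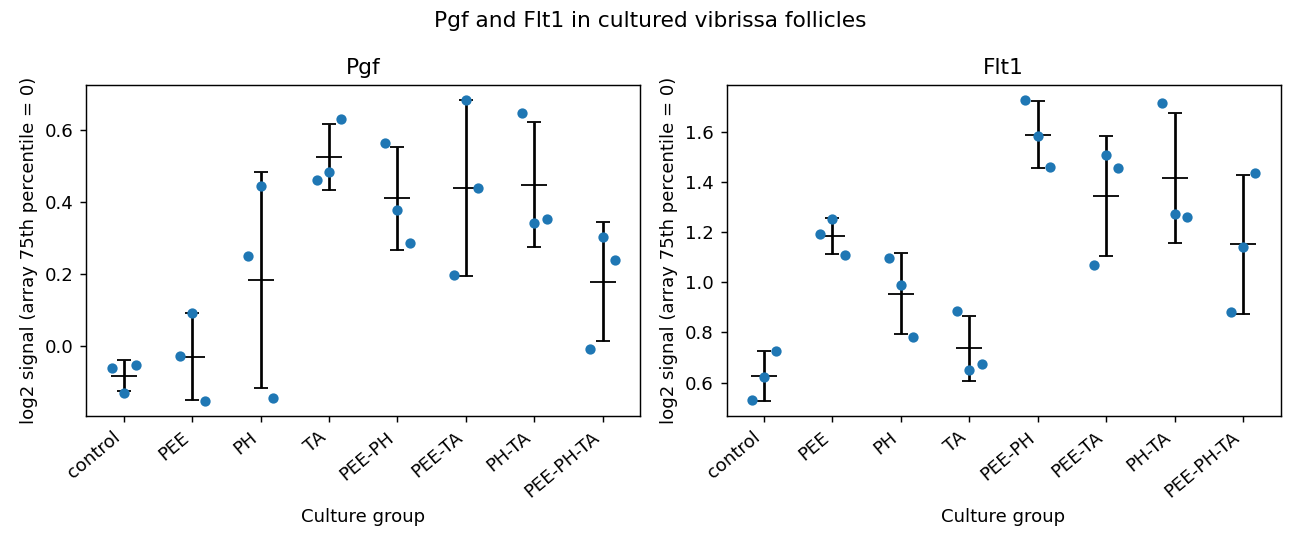
Log2 signal of Pgf and Flt1 relative to the 75th percentile of each array, by culture group. Points are arrays, lines the mean and SD of 3 arrays; the mean of Pgf with all 3 compounds lies below its means with any 2, but single arrays overlap for PEE-PH and PEE-TA, though not for PH-TA, and none of these differences passed.

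All 3 compounds were also tested against the sum of the single compounds. The difference from the sum was -0.67 ± 0.28 for Pgf (limma, adjusted p = 0.83) and -0.47 ± 0.29 for Flt1 (0.869), and neither passed. For the pairs it was 0.17 ± 0.20 (PEE-PH, 0.788), -0.14 (PEE-TA, 0.878) and -0.34 (PH-TA, 0.81) for Pgf. For Flt1 it was 0.08 ± 0.21 (0.923), 0.05 (0.964) and 0.35 (0.824). Against the pairs, Pgf with PEE-PH-TA was -0.23 against PEE-PH (0.4), -0.26 against PEE-TA (0.439) and -0.27 against PH-TA (0.215). Flt1 was -0.44 (0.133), -0.19 (0.604) and -0.26 (0.25), none passing.

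Of the 10 VEGF family ligands and receptors measured, Flt1 and the co-receptor Nrp1 (0.26, limma, adjusted p = 0.0327) rose with PEE-PH-TA, while the lymphatic growth factors Vegfc (-0.70, 0.000659) and Vegfd (-0.50, 0.00491) fell. Vegfa, the main endothelial growth factor (0.32, 0.198), and the receptor Kdr (-0.15) did not pass. Vegfc and Vegfd also fell with PEE (-0.52 and -0.46), PEE-PH (-0.76 and -0.52), PEE-TA (-0.60 and -0.51) and PH-TA (-0.55 and -0.41). Members that rose and fell were 2 and 2 with PEE, 0 and 1 with PH, 1 and 0 with TA, 3 and 2 with PEE-PH, 4 and 2 with PEE-TA, 3 and 2 with PH-TA, and 2 and 2 with PEE-PH-TA. Adjusted over the list alone they were 2 and 2, 0 and 2, 1 and 1, 3 and 2, 4 and 2, 3 and 2, and 2 and 2. For the average effects they were 3 and 2 with PEE, 1 and 2 with PH, and 1 and 0 with TA, and over the list alone 4 and 2, 1 and 2, and 1 and 0. With replicate number as a block Vegfc passed with PH too (-0.42, adjusted p = 0.0287 against 0.0523). None passed in the 4 tests of sums, but Vegfd did over the list alone with all 3 compounds (0.80, limma, adjusted p = 0.0237). The study may have chosen these genes on these samples, so list-alone counts are not independent. The list did not pass against control (lowest camera adjusted p 0.0551, PEE-TA). Against PEE-PH its median with PEE-PH-TA was -0.12 (0.0479, but 0.347 with an estimated correlation), with 0 members past the threshold by either adjustment. Against PEE-TA it was -0.06 (0.0184, but 0.21 with an estimated correlation), where Kdr passed over the list alone (-0.55, 0.00403) and not over all genes (0.076). Against PH-TA the list gave 0.241 and Kdr fell by 0.44 (0.0303).

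In follicles with all 3 compounds, the glutathione transferases Gsta3 (3.82 ± 0.22, limma, adjusted p = 1.36e-08) and Gsta2 (2.49 ± 0.18, 1.19e-07), the quinone reductase Nqo1 (1.97 ± 0.13, 3.88e-08), the cystine transporter Slc7a11 (2.10 ± 0.18, 4.9e-07) and the sulfiredoxin Srxn1 (1.53 ± 0.09, 1.36e-08) rose against control, n = 3 arrays per group. All 5 are known targets of the oxidative stress factor NRF2. The AHR repressor Ahrr (1.70 ± 0.28, 0.000463), the neuropeptide precursor Tac1 (1.62 ± 0.34, 0.00269), the cytokine Il19 (1.60 ± 0.30, 0.00121) and the prolactin family member Prl8a9 (1.75 ± 0.44, 0.00958) rose as well. The interferon Ifnb1 (-2.91 ± 0.48, 0.00045), the chemokines Ccl12 (-2.95 ± 0.27, 1.48e-06) and Cxcl9 (-2.78 ± 0.75, 0.0163), the antiviral genes Mx1 (-2.50 ± 0.45, 0.00097), Tgtp2 (-2.53 ± 0.49, 0.00167) and Ifi206 (-2.37 ± 0.34, 0.000149), and the growth factor of myeloid cells Csf2 (-2.42 ± 0.40, 0.000454) fell. For genes dim on all arrays of the lower group, the fold is a lower bound: the mean of the brighter group against, for each array, the higher of the lowest signal among probes well above background and the signal of the dim probe itself. By it the microtubule gene Map7d2 was at least 1.22-fold, the receptor Gpr20 at least 2.34-fold and the neurofilament gene Nefl at least 1.33-fold higher. The nucleoside transporter Slc28a2 was at least 5.30-fold, Ifit1bl1 at least 2.01-fold, Ms4a4d at least 4.68-fold, the RNA helicase Ddx60 at least 5.13-fold and the GTPase Gbp11 at least 3.60-fold lower.

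Of 30 NRF2 target genes measured, 27 rose with PEE-PH-TA and 0 fell (27 and 0 adjusted over the list alone), with a median of 0.88 (limma camera, adjusted p = 2.05e-34, and 0.0032 with an estimated correlation). Genes of cholesterol synthesis and SREBP2 targets followed, with 21 of 24 up (23 over the list alone), among them the mevalonate enzyme Mvd (1.13 ± 0.12, 6.14e-06); their median was 0.63 (5.79e-23, and 0.0217 with an estimated correlation). Among vitamin E handling and antioxidant genes 10 of 29 rose (11 over the list alone), including catalase Cat (1.08 ± 0.10) and the plasma peroxidase Gpx3 (1.00 ± 0.19), median 0.15 (1.02e-04, and 0.00508 with an estimated correlation). Of 27 interferon response genes 26 fell and 0 rose (27 over the list alone), such as Mx1 and Ifit1 (-2.09 ± 0.41), with a median of -1.76, adjusted p = 6.26e-22, but 0.205 with an estimated correlation. Their medians by slide were -1.89, -1.58 and -1.79. Of 36 cell cycle genes 29 fell (32 over the list alone), including the kinetochore gene Cenpf (-0.74 ± 0.11) and the mitotic kinase Aurka (-0.69 ± 0.11), median -0.52, 6.26e-22, but 0.101 with an estimated correlation. Of 34 inflammatory cytokines and NF-kB targets 17 fell and 1 rose (20 and 1 over the list alone), the risen one being Il19, median -0.70, 3.72e-08, but 0.382 with an estimated correlation.

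Of 20 hair matrix and shaft regulators 8 rose with PEE-PH-TA (10 over the list alone), such as Msx2 (0.91 ± 0.24, limma, adjusted p = 0.0139) and Foxn1 (0.80 ± 0.23, 0.0217), both needed for shaft differentiation, with a list median of 0.38 (2.51e-04, but 0.382 with an estimated correlation). Of 15 inner root sheath markers 7 rose (7 over the list alone), such as the sheath keratin Krt25 (0.76 ± 0.16, 0.00363) and the deiminase Padi3 (0.66), median 0.38 (5.1e-04, but 0.382 with an estimated correlation). Of 16 hair shaft keratins only Krt85 passed, and it fell by 0.31 (0.0314), while the list median was 0.46 (0.0406, but 0.658 with an estimated correlation). Over the list alone 0 shaft keratins passed. Of 21 macrophage and immune markers 9 fell (10 over the list alone), such as Aif1 (-0.90 ± 0.11), median -0.37 (1.44e-04, but 0.382 with an estimated correlation). Of 11 melanocyte markers 3 rose (5 over the list alone), such as Gpr143 (1.42 ± 0.24) and Dct (0.68), median 0.21 (0.0102, but 0.279 with an estimated correlation). Of 20 skeletal muscle markers 2 rose (2 over the list alone), median 0.60 (0.00157, but 0.558 with an estimated correlation). Of 19 pantothenate and coenzyme A genes 4 rose (5 over the list alone), such as the acetyl-CoA synthetase Acss2 (1.32) and the pantothenate kinase Pank1 (0.47), median 0.12 (0.0214, but 0.259 with an estimated correlation).

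In total 1717 genes rose and 1925 fell with PEE-PH-TA against control by limma, 112 and 310 of them at least 2-fold. The balance turned to 2036 and 1733 with quantile normalization and 1793 and 1604 in the authors' value table. Without control replicate 3 the total was 2376, and without replicate numbers 1, 2 and 3 it was 1547, 1407 and 1917. Prl8a9 lost its call without control replicate 1 (adjusted p = 0.0599), and Cxcl9 lost it without PEE-PH-TA replicate 1 (0.0673), 1 of the 2 arrays that ended it.

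**Figure D3:**
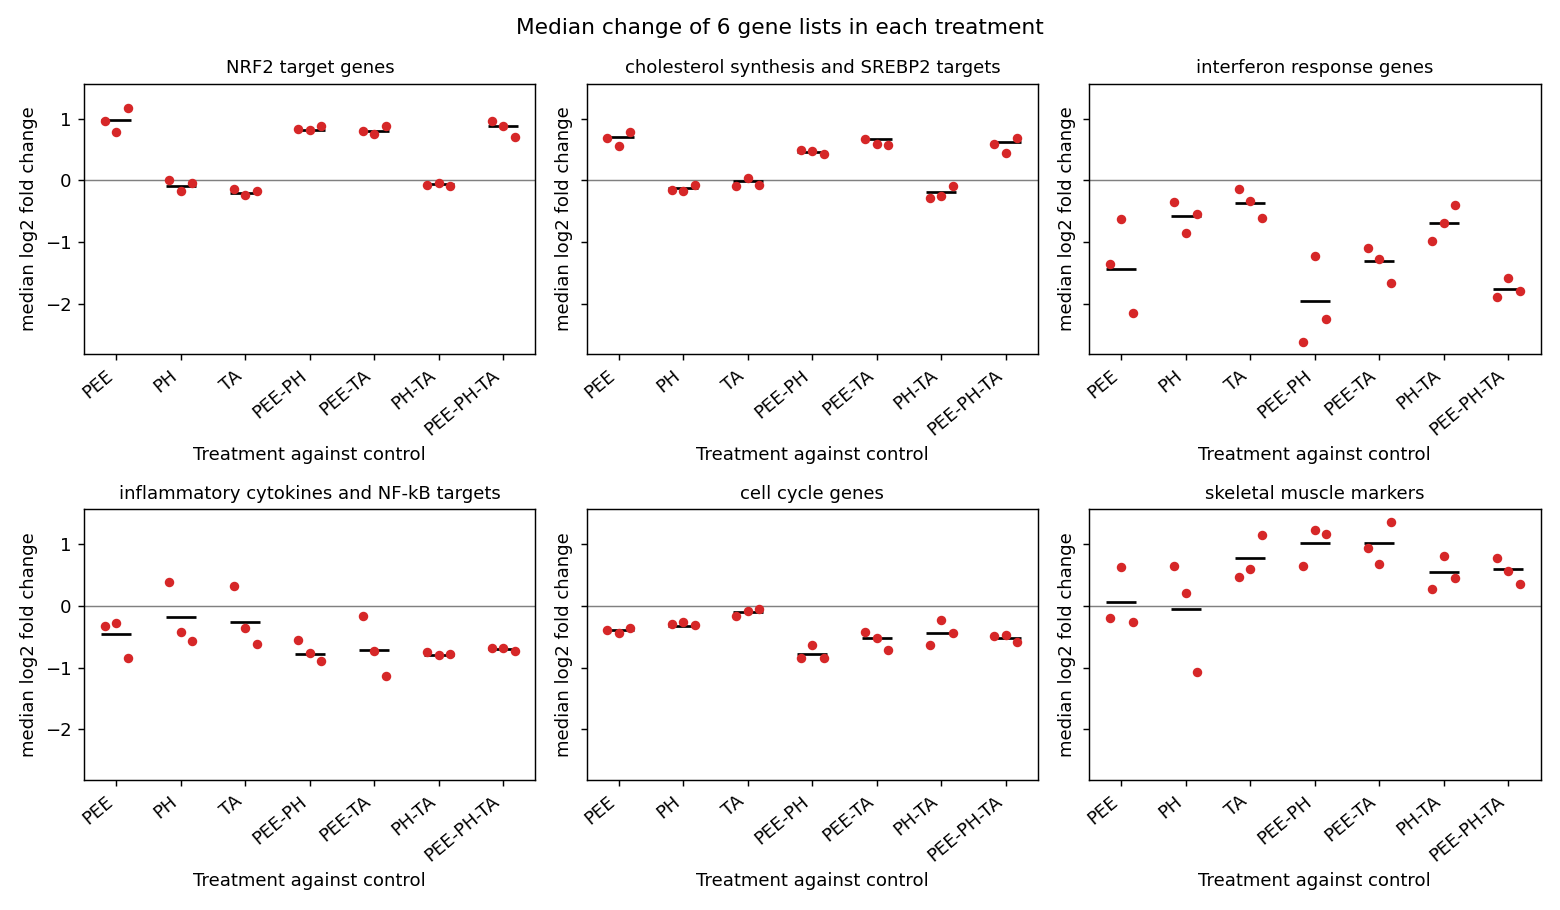
Median log2 fold change against control of 6 gene lists in the 7 treatments, on the vertical axis. Bars show 3 arrays per group and points the medians within each slide; NRF2 and cholesterol genes are high in the 4 treatments with PEE.

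Of the 3 average effects, that of PEE over its 4 backgrounds had the most genes changed at least 2-fold. Gsta3 (NM_001077353, chromosome 1, 21255189 to 21255248 in mm9) rose by 3.99 ± 0.11 (limma, adjusted p = 3.13e-14), Gsta2 by 2.73 ± 0.09 (2.47e-13), Slc7a11 by 2.36 ± 0.09 (6.8e-13), Nqo1 by 1.99 ± 0.06 (1.8e-13), Gsta4 by 1.95 ± 0.07 (5.56e-13), the haem oxygenase Hmox1 by 1.95 ± 0.05 (3.13e-14) and Srxn1 by 1.57 ± 0.05, over 12 arrays with and 12 without PEE. By the bound for average effects the neurofilament gene Nefm was at least 3.93-fold and Map7d2 at least 1.56-fold higher. Gpr20 was at least 2.96-fold and Nefl at least 1.76-fold higher. Chemokines and interferon genes fell: Ccl12 (-2.32 ± 0.13, 3.18e-10), Cxcl9 (-2.19 ± 0.38), Cxcl10 (-1.94 ± 0.35, 0.000404), Tgtp2 (-1.85) and the platelet chemokine Ppbp (-1.85 ± 0.10, 1.32e-10). The epidermal protease Klk14 (-2.15 ± 0.11, 7.3e-11) fell too, and Ifnb1 was at least 2.36-fold, Ms4a4d at least 2.48-fold, Slc28a2 at least 3.1-fold, the retinoic acid hydroxylase Cyp26a1 at least 1.61-fold, Ifit1bl1 at least 1.23-fold and Ceacam15 at least 1.30-fold lower.

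Of the 30 NRF2 target genes 28 rose with PEE on average (28 over the list alone), median 0.88, limma camera adjusted p = 6.95e-44, and 7.06e-04 with an estimated correlation. Of 24 cholesterol genes 23 rose (23 over the list alone), among them Mvd (1.17 ± 0.06, 5.37e-11), median 0.73 (6.16e-34, and 0.00385 with an estimated correlation). Fatty acid synthesis and LXR targets gave 11 of 20 up (13 over the list alone), such as Acss2 (1.20 ± 0.06) and the desaturase Scd2 (0.64), median 0.26 (6.65e-09, and 0.0137 with an estimated correlation). Of 29 antioxidant genes 15 rose (16 over the list alone), such as Cat (1.04 ± 0.05) and Gpx2 (0.89 ± 0.08), median 0.16 (1.16e-06, and 7.06e-04 with an estimated correlation). Of 22 xenobiotic genes 11 rose and 5 fell (12 and 6 over the list alone), with Ahrr up (1.42 ± 0.14) and the epidermal cytochromes Cyp2b19 (-0.49) and Cyp2s1 (-0.48) down, median 0.29 (0.00568, and 0.0338 with an estimated correlation). All 27 interferon genes fell (27 over the list alone), median -1.19, 1.45e-22, but 0.191 with an estimated correlation, and by slide -1.35, -0.66 and -1.46. Of 36 cell cycle genes 33 fell (35 over the list alone), such as Ccnb2 (-0.50) and Birc5 (-0.49), median -0.33, 2.58e-22, but 0.0959 with an estimated correlation. In total 2826 genes rose and 3136 fell, 57 and 129 of them at least 2-fold, and 3121 and 2674 with normexp background. The total was 3831, 2959 and 4189 without replicate numbers 1, 2 and 3.

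With PEE alone Gsta3 rose by 4.28 ± 0.22 (limma, adjusted p = 1.51e-09) and Gsta2 by 3.14 ± 0.18 (5.63e-09), n = 3 arrays per group, while Map7d2 was at least 2.92-fold, Nefl at least 2.62-fold and Gpr20 at least 3.92-fold higher. Ccl12 (-2.47 ± 0.27, 8.8e-06), Cxcl10 (-2.52 ± 0.71, 0.0287) and Ms4a4d (-2.57 ± 0.69, 0.0228) fell, Ifit1bl1 was at least 1.60-fold and Ddx60 at least 4.08-fold lower. Of 30 NRF2 targets 28 rose (28 over the list alone), median 0.98, 2.17e-44, and 7.95e-04 with an estimated correlation. Of 24 cholesterol genes 22 rose (22 over the list alone), median 0.69 (1.43e-29, and 0.00585 with an estimated correlation). Interferon genes gave 24 of 27 down (27 over the list alone), median -1.44 (3.42e-22, but 0.154 with an estimated correlation), and -1.35, -0.63 and -2.15 by slide. Cell cycle genes gave 23 of 36 down (28 over the list alone), median -0.39 (4.39e-19, but 0.113 with an estimated correlation). Of 16 endothelial markers 10 rose (13 over the list alone), such as Vwf (0.90, 0.0422, but 0.0509 with replicate number as a block) and Tek (0.71), median 0.53 (1.9e-07, but 0.238 with an estimated correlation). Of 11 blood and erythroid genes 5 rose (7 over the list alone), such as the globin Hbb-bt (0.73), median 0.55 (3.36e-06, and 0.0478 with an estimated correlation).

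In all 1148 genes rose and 1256 fell with PEE alone by limma, 113 and 178 at least 2-fold. With normexp background correction 4092 rose and 1793 fell. The total was 1430 without control replicate 1, 1348 without control replicate 2, 1479 without PEE replicate 2 and 1543 without PEE replicate 3, 636, 522 and 1379 without replicate numbers 1, 2 and 3, and 886 with array signal as a covariate. Without PEE replicate 3 the adjusted p was 0.121 for Ms4a4d and 0.152 for Cxcl10, whose calls 3 and 4 of the 6 arrays ended. Both also lost their calls without each replicate number. Ifit1bl1 lost its call without number 1 (limma, adjusted p = 0.0889) and Ddx60 without number 3 (0.064).

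PH, a form of vitamin B6, raised Tac1 on average over the backgrounds (1.25 ± 0.17, limma, adjusted p = 5.98e-05) together with the neuroserpin gene Serpini1 (1.08 ± 0.13, 3.08e-05), Angptl7 (0.96), Ces1a (0.95), the corneal proteoglycan Kera (0.95), Gask1a (0.91) and Speer2 (0.90). The homeobox gene Hoxc6 was at least 1.12-fold, Speer6-ps1 at least 1.17-fold, Pou2af1 at least 1.47-fold and Scgb3a1 at least 1.31-fold higher, but with normexp background their values were -0.09, -0.08, -0.05 and -0.06. Ttll9 also passed, dim in the lower group and with no bound above 1, and had -0.09 with normexp. There Hoxc6 (0.0229) and Ttll9 (0.0219) passed in the opposite direction, so their direction is not settled. The retinol binding protein gene Rbp7 fell by 1.97 ± 0.12 (1.63e-08), the interferon gene Ifi27l2a by 1.01 ± 0.12 (3.08e-05) and the gelatinase Mmp9 by 0.84 ± 0.08 (4.57e-06). Plac8 (-0.93), Wfdc17 (-0.82) and the chemokines Ccl8 (-0.84) and Ccl21a (-0.89) fell, and Tac4 was at least 1.70-fold, Ifnb1 at least 1.48-fold and Slc16a14 at least 1.26-fold lower. Slc28a2 and C1qtnf9 passed as lower, without a bound, as 2 groups without PH were dim too. Ccl21a lost its call without PH-TA replicate 1 (0.0665), and 13 of the 24 arrays ended it. Without at least 1 replicate number Gask1a, Speer6-ps1, Pou2af1, Ttll9, Ccl21a, Slc16a14, Wfdc17 and Ifnb1 lost their calls, and Slc28a2 without each of the 3.

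Of 16 hair shaft keratins 10 rose with PH on average (11 over the list alone), such as Krt82 (0.71 ± 0.14, limma, adjusted p = 0.00108) and Krt32 (0.65 ± 0.15), median 0.40 (1.55e-04, but 0.55 with an estimated correlation). Of 20 hair matrix and shaft regulators 12 rose (13 over the list alone), with Foxn1 (0.68 ± 0.11) and the Wnt effector Lef1 (0.54), median 0.22 (6.6e-05, but 0.443 with an estimated correlation). Of 15 inner root sheath markers 9 rose (10 and 1 down over the list alone), such as Krt25 (0.58 ± 0.08), median 0.26 (1.67e-04, but 0.443 with an estimated correlation). Cell cycle genes fell in 27 of 36 cases (30 over the list alone), median -0.25 (1.18e-11, but 0.443 with an estimated correlation). Cholesterol genes, which rose with PEE, fell with PH in 16 of 24 cases (18 over the list alone), median -0.15 (6.6e-05, but 0.443 with an estimated correlation). Interferon genes fell in 11 of 27 cases (18 over the list alone), median -0.43 (6.6e-05, but 0.693 with an estimated correlation). Of 31 vitamin B6 and PLP enzyme genes 6 rose and 4 fell (6 and 4 over the list alone), and as a list they did not pass (0.383). In total 3059 genes rose and 3839 fell, only 10 and 18 of them at least 2-fold. The direction of that balance depended on scaling: 3888 rose and 2814 fell with quantile normalization, 3585 and 2653 in the authors' value table and 3688 and 8911 with normexp. The total was 2263, 3681 and 4841 without replicate numbers 1, 2 and 3. With the signal of each array as a covariate, chosen after the data were seen, 258 genes passed.

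PH alone raised Tac1 (1.86 ± 0.34, limma, adjusted p = 0.00423), the piRNA pathway gene Piwil2 (1.66 ± 0.30, 0.00403), Speer2 (1.53) and Fibin (1.49 ± 0.24, 0.00237), and Speer1 was at least 2.04-fold higher, n = 3 arrays per group. Rbp7 (-2.10 ± 0.23, 2.23e-04), Hoxd3os1 (-1.42), the histone gene H2bc23 (-1.35) and L1td1 (-1.30) fell, and Chp2 was at least 1.53-fold lower. Of 15 inner root sheath markers 4 rose (8 over the list alone), such as Krt25 (0.82 ± 0.16, 0.00845) and Padi3 (0.66, 0.04), median 0.35 (6.52e-05, but 0.506 with an estimated correlation), with 0.12, 0.17 and 0.79 by slide. Cell cycle genes fell in 11 of 36 cases (21 over the list alone), median -0.33 (6.2e-11, but 0.506 with an estimated correlation). Macrophage markers fell in 2 of 21 cases (4 over the list alone), Itgam (-0.47) and Aif1 (-0.41), median -0.21 (0.00226, but 0.686 with an estimated correlation). In total 352 genes rose and 806 fell, 21 and 153 at least 2-fold, and 518 and 621 with quantile normalization or 398 and 557 in the authors' value table. The total was 767, 623 and 324 without control replicates 1, 2 and 3, 279 without PH replicate 2 and 711 without PH replicate 3. It was 513, 0 and 178 without replicate numbers 1, 2 and 3 (so that without number 2, with 2522 at an unadjusted p under 0.05, each gene call ended), 634 with array signal as a covariate and 733 without the filter on dim probes. Without PH replicate 2 the adjusted p was 0.154 for Speer1, 0.131 for H2bc23, 0.13 for L1td1 and 0.071 for Hoxd3os1, and without control replicate 3 it was 0.121 for Chp2. The calls of these 5 genes ended without 5, 5, 5, 2 and 4 of the 6 arrays.

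TA, a vitamin E ester, changed 1762 genes on average, the fewest of the 3 average effects, although its count was above that of PEE with normexp (7459 against 5795) and without the filter on dim probes (7131 against 5215). Hair genes stood among those that rose. The hair shaft keratins Krt31 (0.51 ± 0.14, limma, adjusted p = 0.0361) and Krt36 (0.48 ± 0.13, 0.0293), the lipoxygenase Alox8 (0.88 ± 0.17, 0.00738), Dclk3 (0.56), Hes2 (0.54), Calhm4 (0.51), Nmrk2 (0.49), Fbp1 (0.48) and the Wnt modulator Sfrp2 (0.45 ± 0.12, 0.0316) rose over 12 arrays with and 12 without TA. The transcription factor gene Ascl4 was at least 1.40-fold and Serpinb13 at least 1.16-fold higher, and the fatty acid receptor Ffar4 (0.49) rose too, but with normexp background their values were -0.03, -0.05 and -0.01. Gdap7 (-0.72), the osteoclast gene Dcstamp (-0.57), the eotaxin Ccl11 (-0.52 ± 0.13, 0.0222), Lilr4b (-0.49), Ovgp1 (-0.49) and the chemokine Ccl3 (-0.63 ± 0.19, 0.0477) fell, and C1ql2 was at least 1.54-fold, Sowaha at least 1.42-fold, Pilrb2 at least 1.40-fold, Smc2os at least 1.34-fold and Muc16 at least 1.26-fold lower. With replicate number as a block Ccl3 had 0.0538. Without control replicate 3 the adjusted p was 0.0593 for Calhm4, 0.0715 for Krt31, 0.0738 for Nmrk2, 0.0606 for Krt36, 0.0946 for Ccl3, 0.0591 for Muc16 and 0.067 for Dcstamp. It was 0.0817 for Ffar4 and 0.0906 for Ovgp1 without PEE-TA replicate 2, and 0.0619 for Sfrp2 without PEE-PH replicate 3. Between 4 (Calhm4) and 18 (Ccl3) of the 24 arrays ended these calls. Without each of the 3 replicate numbers in turn Krt31, Krt36, Sfrp2, Calhm4, Nmrk2, Ascl4, Serpinb13, Dcstamp, Ccl3, Ccl11, Lilr4b, C1ql2 and Smc2os lost their calls every time, and of the genes above only Sowaha never did.

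Of 27 PPAR target genes 5 rose with TA on average (6 over the list alone), such as the carnitine carrier Slc25a20 (0.18, limma, adjusted p = 0.0496, but 0.0574 with replicate number as a block), median 0.12 (4.2e-06, and 0.00377 with an estimated correlation). Of 15 inner root sheath markers 10 rose and 1 fell (13 and 1 over the list alone), with Krt25 (0.50 ± 0.08, 0.003) and Padi3 (0.49) up and Ctsl (-0.18) down, median 0.34 (2.35e-10, but 0.107 with an estimated correlation), and 0.33, 0.28 and 0.39 by slide. Of 16 hair shaft keratins 8 rose (14 over the list alone), median 0.43 (2.78e-09, but 0.279 with an estimated correlation). Of 20 hair matrix regulators 9 rose (12 over the list alone), such as Lef1 (0.55 ± 0.12, 0.0119), median 0.28 (8.38e-09, but 0.182 with an estimated correlation). Wnt pathway genes gave 9 up and 1 down of 29 (13 and 1 over the list alone), with Wnt16 (-0.34) down, median 0.19 (8.38e-09, but 0.087 with an estimated correlation). Skeletal muscle markers rose in 3 of 20 cases (15 over the list alone), such as the myogenic factor Myog (0.66 ± 0.11, 0.00297) and desmin Des (0.56), median 0.48 (2.35e-10, but 0.31 with an estimated correlation), and 0.37, 0.16 and 0.87 by slide. In total 614 genes rose and 1148 fell, 0 and 4 at least 2-fold; 819 and 954 with quantile normalization, 739 and 856 in the authors' value table and 1498 and 5961 with normexp. The total was 922 without control replicate 3, 1116 without PEE replicate 1, 1091 without PH-TA replicate 1, 978 without PEE-TA replicate 2, 1039 without PEE-PH replicate 3, and 302, 184 and 69 without replicate numbers 1, 2 and 3. With array signal as a covariate it was 6.

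TA alone raised Klhl30 (1.45 ± 0.30, limma, adjusted p = 0.0222), Piwil2 (1.40 ± 0.30, 0.0254), the cartilage matrix gene Cilp (1.37 ± 0.29, 0.0266) and the muscle gene Mybph (1.29 ± 0.23, 0.0107), and Ascl4 was at least 1.63-fold higher, n = 3 arrays per group. The long noncoding RNA Lncpint (-1.36 ± 0.17, 0.00127), Mir142hg (-1.28 ± 0.18, 0.00308) and the histone gene H2ac6 (-1.39, 0.0196) fell, and H2bc23 was at least 2.42-fold and the natural killer receptor Klrd1 at least 2.08-fold lower. NRF2 targets, which rose with PEE, fell with TA in 3 of 30 cases (10 down and 1 up over the list alone), including Gsta3 (-0.96, 0.037) and Hmox1 (-0.85, 0.00148), median -0.20 (4.85e-06, but 0.34 with an estimated correlation). Inner root sheath markers rose in 3 of 15 cases (10 up and 1 down over the list alone), Krt25 (0.71) and Krt71 (0.58) among them, median 0.39 (2.14e-07, but 0.317 with an estimated correlation). Wnt genes gave 2 of 29 up (7 over the list alone), Rspo3 (0.84) and Lgr5 (0.72), median 0.24 (6.36e-07, but 0.289 with an estimated correlation). Muscle markers gave 2 of 20 up (6 over the list alone), Myog (1.18, 0.0135) and the embryonic myosin Myh3 (1.02, 0.0185), median 0.78 (6.32e-10, but 0.368 with an estimated correlation).

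In total 88 genes rose and 315 fell with TA alone by limma, 16 and 60 at least 2-fold, and 136 and 283 with quantile normalization. The total was 37 and 14 without control replicates 2 and 3, and 170, 173 and 95 without TA replicates 1, 2 and 3. It was 54, 8 and 4 without replicate numbers 1, 2 and 3, 150 with array signal as a covariate and 165 without the filter on dim probes. Without control replicate 3 the adjusted p was 0.121 for Klhl30, 0.146 for Piwil2 and Cilp, 0.0759 for Mybph and 0.128 for H2bc23. It was 0.136 for Ascl4 without TA replicate 2, 0.151 for Klrd1 without TA replicate 3 and 0.0862 for H2ac6 without control replicate 2. Between 2 (Mybph) and 6 (H2bc23) of the 6 arrays ended these calls.

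With PEE-PH, Gsta3 (3.31 ± 0.22, limma, adjusted p = 3.64e-08), the mast cell protease Mcpt1 (2.92 ± 0.70, 0.00346), Slc7a11 (2.17 ± 0.18, 2.42e-07) and Tac1 (2.16 ± 0.34, 1.04e-04) rose against control, and Map7d2 was at least 1.20-fold higher, though -0.08 with normexp background, n = 3 arrays per group. Cxcl9 (-3.27 ± 0.75, 0.00271) and Cxcl10 (-3.19 ± 0.71, 0.00207) fell, and Ifnb1 was at least 6.12-fold, Slc28a2 at least 5.69-fold and Ddx60 at least 5.75-fold lower. NRF2 targets rose in 26 of 30 cases (27 over the list alone), median 0.82 (2.96e-21, and 0.0321 with an estimated correlation), and antioxidant genes rose in 14 and fell in 1 of 29 (14 and 2 over the list alone), median 0.22 (0.00144, and 0.0336 with an estimated correlation). Of 36 cell cycle genes 35 fell (35 over the list alone), such as Birc5 (-1.10) and Aurka (-1.07), median -0.78 (1.55e-19, but 0.127 with an estimated correlation). Interferon genes fell in 26 of 27 cases (26 over the list alone), median -1.96 (1.04e-13, but 0.267 with an estimated correlation), and -2.62, -1.22 and -2.25 by slide. Cholesterol genes rose in 17 of 24 cases (21 over the list alone), median 0.46 (2.08e-12, but 0.117 with an estimated correlation). Hair matrix regulators rose in 11 of 20 cases (14 over the list alone), such as Foxn1 (1.10) and Lef1 (0.99), median 0.48 (1.21e-04, but 0.267 with an estimated correlation). Ribosomal protein genes fell in 23 of 32 cases (25 over the list alone), median -0.23 (5.97e-07, but 0.267 with an estimated correlation). Muscle markers rose in 10 of 20 cases (15 over the list alone), median 1.02 (7.56e-07, but 0.294 with an estimated correlation). In total 3293 genes rose and 4621 fell, 280 and 822 at least 2-fold, and 4196 and 3486 with quantile normalization, 4016 and 3279 in the authors' value table or 3392 and 7881 with normexp. With array signal as a covariate they were 1206 and 2069, and without the filter on dim probes 3246 and 9464. The total was 4346 and 3681 without replicate numbers 1 and 2.

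With PEE-TA, Gsta3 (3.55 ± 0.22, limma, adjusted p = 2.57e-08), Gsta2 (2.19 ± 0.18, 5.7e-07) and Slc7a11 (2.15 ± 0.18, 4.28e-07) rose, and Gpr20 was at least 3.39-fold higher, n = 3 arrays per group, and Map7d2 passed with a bound close to 1. Csf2 (-2.79 ± 0.40, 1.15e-04), Ccl12 (-2.73 ± 0.27, 3.25e-06) and Ms4a4d (-3.26 ± 0.69, 0.00255) fell, and Slc28a2 was at least 5.52-fold and the neutrophil gene Retnlg at least 2.34-fold lower. NRF2 targets rose in 27 of 30 cases (27 over the list alone), median 0.81 (7.02e-29, and 0.00393 with an estimated correlation), and cholesterol genes in 22 of 24 (24 over the list alone), median 0.67 (4.3e-24, and 0.0179 with an estimated correlation). Antioxidant genes rose in 11 of 29 cases (11 over the list alone), median 0.17 (3.52e-05, and 0.00393 with an estimated correlation), and fatty acid synthesis genes in 11 of 20 (11 up and 1 down over the list alone), median 0.28 (6.48e-08, and 0.0188 with an estimated correlation). PPAR targets rose in 8 of 27 cases (10 over the list alone), such as the lipid droplet gene Plin4 (0.57), median 0.17 (9.26e-04, and 0.0182 with an estimated correlation). Interferon genes fell in 26 of 27 cases (26 over the list alone), median -1.30 (2.34e-11, but 0.245 with an estimated correlation), and cell cycle genes in 32 of 36 (34 over the list alone), median -0.52 (4e-17, but 0.163 with an estimated correlation). Hair matrix regulators rose in 12 of 20 cases (12 over the list alone), median 0.47 (5.97e-06, but 0.243 with an estimated correlation). Endothelial markers rose in 12 and fell in 1 of 16 cases (12 and 1 over the list alone), median 0.59 (1.16e-05, but 0.245 with an estimated correlation). In total 2253 genes rose and 3373 fell, 176 and 508 at least 2-fold, and 2830 and 2603 with quantile normalization or 2635 and 2402 in the authors' value table. The total was 3503 without control replicate 3, 3177 without PEE-TA replicate 2, 1305 and 2301 without replicate numbers 2 and 3, and 3710 with array signal as a covariate.

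With PH-TA, the pair without PEE, Mcpt1 (2.99 ± 0.70, limma, adjusted p = 0.00438), the cation transporter Slc22a2 (2.38 ± 0.69, 0.0156), the cartilage matrix gene Comp (2.20 ± 0.39, 8.05e-04) and Fibin (2.13 ± 0.24, 4.84e-05) rose, n = 3 arrays per group, and the spondin Spon1 was at least 1.72-fold higher, though -0.08 with normexp background. Rbp7 (-2.27 ± 0.23, 3.74e-05), Ccdc172 (-1.80), the cytochrome Cyp2a5 (-1.72 ± 0.29, 4.9e-04) and Ifnb1 (-1.69 ± 0.48, 0.0134) fell, and Slfn4 was at least 2.44-fold lower. Hair shaft keratins rose in 7 of 16 cases (12 over the list alone), such as Krt82 (1.20) and Krt32 (1.08), median 0.79 (3.8e-05, but 0.367 with an estimated correlation). Inner root sheath markers rose in 10 and fell in 1 of 15 (10 and 1 over the list alone), median 0.64 (1.27e-05, but 0.294 with an estimated correlation), and hair matrix regulators rose in 10 of 20 (11 over the list alone), such as Lef1 (1.23) and Foxn1 (1.19), median 0.53 (1.71e-05, but 0.294 with an estimated correlation). Wnt genes rose in 15 of 29 cases (15 up and 1 down over the list alone), median 0.45 (2.77e-06, but 0.294 with an estimated correlation). Dermal papilla markers rose in 9 and fell in 2 of 24 cases (10 and 2 over the list alone), with the Wnt inhibitor Wif1 (0.99) and the phosphatase Alpl (0.97) up and Hhip (-0.63) down, median 0.17 (0.00738, but 0.294 with an estimated correlation). Cell cycle genes fell in 28 of 36 cases (30 over the list alone), median -0.43 (2.52e-10, but 0.294 with an estimated correlation). Cholesterol genes fell in 12 of 24 cases (12 over the list alone), median -0.19 (0.00697, but 0.468 with an estimated correlation), and interferon genes in 8 of 27 (8 over the list alone), median -0.69 (7.32e-04, but 0.541 with an estimated correlation).

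In total 2661 genes rose and 3860 fell with PH-TA by limma, 196 and 452 at least 2-fold. The balance was 3463 and 2807 with quantile normalization, 3188 and 2549 in the authors' value table and 2981 and 9043 with normexp. The total was 4258 without control replicate 3 and 3882 without PH-TA replicate 1, 2359 and 2281 without replicate numbers 1 and 2, 118 with array signal as a covariate and 12649 without the filter on dim probes. The adjusted p was 0.106 for Slc22a2 without control replicate 3, 0.0982 for Ccdc172 without PH-TA replicate 3, 0.0718 for Slfn4 without PH-TA replicate 1 and 0.0634 for Ifnb1 without PH-TA replicate 2. Of the 6 arrays 2, 2, 1 and 1 ended these calls.

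Pairs and all 3 compounds were then tested against the sum of the single compounds, on log2 values. Hmox1 (NM_010442, chromosome 8, 77624406 to 77624466 in mm9) lay 1.43 ± 0.15 above the sum with PH-TA (limma, adjusted p = 5.83e-04), as did Gfod1 (1.16 ± 0.15, 0.00462) and the adaptor gene Lime1 (0.68 ± 0.10, 0.0152), the only 3 genes past the threshold, n = 3 arrays in each of 4 groups. Hmox1 fell with TA alone, which raises this difference, so it need not be a rise over control. With PEE-TA 15 genes lay below the sum and 0 above, among them C2cd4c (-1.48 ± 0.24, 0.0317), the defensin Defa1 (-1.33 ± 0.24, 0.0395), the red cell gene Alas2 (-1.23 ± 0.21, 0.0377) and Il12b (-1.20 ± 0.20, 0.0377), a subunit of interleukins 12 and 23. With PEE-PH limma called 0 genes, although 2473 had an unadjusted p under 0.05, the smallest being those of 2 unnamed transcripts (-0.98 and -0.70) and Il12b (-1.23 ± 0.20), all with adjusted p = 0.0627. With replicate number as a block 39 passed, and with normexp background 424 lay above and 4866 below the sum, while quantile normalization and the authors' value table gave 0 each. For all 3 compounds limma called 0 genes, with 1307 at an unadjusted p under 0.05, 0 with replicate number as a block, 0 with quantile normalization, 0 in the authors' value table and 1 with normexp. The smallest p-values there were those of Gfod1 (1.34 ± 0.21, 0.148), Hmox1 (1.26 ± 0.22, 0.192) and AK079898 (1.08 ± 0.20, 0.24).

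Of 39 gene lists, 2, 2, 0 and 0 passed with an estimated correlation in the sums of PEE-PH, PEE-TA, PH-TA and all 3 compounds. Blood and erythroid genes lay below the sum with PEE-PH, with 0 of 11 members past the threshold (7 down over the list alone), median -0.64 (limma camera, adjusted p = 2.55e-09, and 0.0241 with an estimated correlation). With PEE-TA 2 of 11 lay below, such as Alas2 (6 over the list alone), median -0.55 (8.75e-09, and 0.0248 with an estimated correlation). PPAR targets lay above the sum, with 0 of 27 members past the threshold in either pair. Their median was 0.22 with PEE-PH and 0.17 with PEE-TA (2.81e-07 and 5.75e-06, and 0.0011 and 0.00384 with an estimated correlation). These pairs share the PEE and control arrays, so they are not independent. Blood genes rose with PEE alone, which lowers both differences. NRF2 targets lay above the sum with PH-TA, 1 of 30 past the threshold (4 over the list alone), median 0.22 (1e-10, but 0.39 with an estimated correlation). With all 3 compounds the medians of endothelial markers (-0.66, 4.29e-09), cell cycle genes (0.31, 2.33e-06) and interferon genes (0.74, 2.08e-04) passed, but had 0.819, 0.899 and 0.899 with an estimated correlation.

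Most of these counts rested on single arrays. The count for PEE-TA was 49 without control replicate 3, 2 without TA replicate 3 and 1 without PEE replicate 1 or PEE-TA replicate 1. It was 0 without any other of the 12 arrays. It was 67 with replicate number as a block, 0 with quantile normalization and 2 in the authors' value table. Without control replicate 2 limma gave adjusted p = 0.159 for Defa1 and 0.136 for Alas2 and Il12b, and without PEE replicate 2 it gave 0.119 for C2cd4c. Each of these 4 lost its call without any of 11 of the 12 arrays. The PEE-PH count was 26 without control replicate 3, 16 without PEE-PH replicate 3 and 1 without PH replicate 1. For PH-TA it was 5 without PH replicate 3 and 9 without PH-TA replicate 3, and 5 genes above and 1 below in the authors' value table. Lime1 lost its call without 7 of 12 arrays (0.0618 without control replicate 2), and Hmox1 and Gfod1 without 0 of them. Without a whole replicate number, though, the count was 3, 1 and 0 (numbers 1, 2 and 3), and Hmox1 lost its call without number 2 (0.4) or 3 (0.203) and Gfod1 without each of them (0.508, 0.508 and 0.0664). For all 3 compounds the count was 1 without PH replicate 1.

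Adding the third compound to a pair changed most where PEE was the addition. Over PH-TA, PEE-PH-TA had higher Gsta3 (3.73 ± 0.22, limma, adjusted p = 1.87e-08), Gsta2 (2.87 ± 0.18, 1.87e-08) and Gsta4 (2.20 ± 0.14, 2.31e-08), and Nefl was at least 1.75-fold and Gpr20 at least 3.08-fold higher, n = 3 arrays per group. Ccl12 fell by 1.97 ± 0.27 (1.52e-04), Ceacam15 was at least 2.04-fold lower, and Slc28a2 at least 2.28-fold, Gpr17 at least 1.35-fold and the urea transporter Slc14a1 at least 1.94-fold lower, though with normexp background these last 3 had 0.03, 0.12 and 0.08. NRF2 targets rose in 26 of 30 cases (27 over the list alone), median 0.78 (9.9e-35, and 0.00305 with an estimated correlation), and cholesterol genes in 23 of 24, such as the lanosterol synthase Lss (1.23 ± 0.08), median 0.80 (6.39e-31, and 0.00896 with an estimated correlation). Dermal sheath and smooth muscle markers fell in 6 of 14 cases (10 down and 1 up over the list alone), such as the tenascin Tnn (-1.20 ± 0.22) and calponin Cnn1 (-1.01 ± 0.23), median -0.37 (3.84e-05, and 0.044 with an estimated correlation). Interferon genes fell in 16 of 27 cases (23 over the list alone), median -0.89 (9.29e-14, but 0.238 with an estimated correlation), and dermal fibroblast genes in 13 of 18, such as Ogn (-1.20) and Fmod (-1.03), median -0.53 (1.16e-09, but 0.196 with an estimated correlation). In total 1899 genes rose and 1084 fell, and 1388 and 1214 with quantile normalization, 1174 and 1078 in the authors' value table or 6734 and 1647 with normexp. The total was 1229 and 1741 without PH-TA replicates 1 and 2 and 1802 without PEE-PH-TA replicate 2, 454 and 238 without replicate numbers 1 and 2, 288 with array signal as a covariate and 8213 without the filter on dim probes.

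Adding TA to PEE-PH raised the matricellular gene Ccn1 (0.86 ± 0.11, limma, adjusted p = 0.00448), H2ac6 (1.24), the G protein regulator Rgs1 (0.90 ± 0.16, 0.0281) and Slc22a6 (0.88), n = 3 arrays per group. Kiss1r (-0.97), Myh3 (-0.90 ± 0.20, 0.0436), the clock output factor Hlf (-0.69 ± 0.13, 0.0371), Podn (-0.58) and the extracellular superoxide dismutase Sod3 (-0.58 ± 0.13, 0.0436) fell. Ribosomal protein genes rose in 2 of 32 cases (27 over the list alone), Rpl11 (0.34) and Rpl5 (0.25), median 0.17 (1.8e-12, but 0.347 with an estimated correlation). Cell cycle genes had 0 of 36 past the threshold (14 up over the list alone), median 0.21 (2.68e-08, but 0.347 with an estimated correlation). In total 151 genes rose and 8 fell, and 216 and 42 with normexp, 322 and 26 with replicate number as a block, 12 and 0 with quantile normalization and 7 and 0 in the authors' value table. The total was 4 and 3 without PEE-PH replicates 1 and 2, 602 without PEE-PH replicate 3, 2 without PEE-PH-TA replicate 1 or 2, and 49 without PEE-PH-TA replicate 3. It was 15 without the filter on dim probes, 0 without each replicate number (2068, 2258 and 4447 at an unadjusted p under 0.05) and 0 with array signal as a covariate (2361). Without PEE-PH replicate 1 the adjusted p was 0.257 for H2ac6 and Kiss1r, 0.244 for Slc22a6, 0.243 for Myh3 and Podn, and 0.214 for Hlf and Sod3. Without PEE-PH replicate 2 it was 0.119 for Rgs1. Ccn1 kept its call without any of the 6 arrays, and between 4 (Hlf) and 6 (Sod3) arrays ended the others.

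Adding PH to PEE-TA raised the myelin and lymphocyte gene Mal (1.07 ± 0.13, limma, adjusted p = 0.00398), Gfod1 (0.81 ± 0.11, 0.00399), Copg2os2 (0.98), Ppbp (0.98) and Abhd11os (0.71), n = 3 arrays per group. Rbp7 (-1.31 ± 0.23, 0.0258), the granzyme Gzmc (-1.0), Myh3 (-1.0 ± 0.20, 0.0414), the cytochrome Cyp2f2 (-0.98) and the lipolysis inhibitor G0s2 (-0.81 ± 0.12, 0.00983) fell. Immediate early genes rose in 2 of 31 cases, Ccn1 (0.68 ± 0.11, 0.0141) and Ccn2 (0.47 ± 0.08, 0.0196), median 0.11 (0.00217, but 0.424 with an estimated correlation). Dermal fibroblast genes had 0 of 18 past the threshold (6 down over the list alone), median -0.35 (2.02e-11, but 0.187 with an estimated correlation). In total 38 genes rose and 15 fell, and 66 and 18 with replicate number as a block, 13 and 9 in the authors' value table and 27 and 17 with normexp. The total was 284, 3 and 5 without PEE-TA replicates 1 to 3, and 6, 27 and 16 without PEE-PH-TA replicates 1 to 3. It was 7, 1 and 0 without replicate numbers 1 to 3 (2545 at an unadjusted p under 0.05 without the last). It was 35 with array signal and 24 without the filter. Without PEE-TA replicate 2 the adjusted p was 0.195 for Copg2os2, 0.192 for Ppbp, 0.157 for Abhd11os and Cyp2f2, 0.162 for Gzmc, 0.227 for Myh3 and 0.0833 for G0s2, and without PEE-TA replicate 3 it was 0.131 for Rbp7. Mal and Gfod1 kept their calls without any of the 6 arrays, but lost them without each number. Between 2 (G0s2) and 6 (Cyp2f2) arrays ended the others.

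Fold changes of a compound were correlated across 22065 genes (not independent replicates) between backgrounds sharing no array. For PEE the 6 correlations had a median of 0.485, from 0.192 between PEE added to PH and PEE added to PH-TA (Spearman -0.00922) to 0.657 between PEE added to PH and PEE added to TA. For PH it was 0.184, from -0.363 between PH added to PEE and to PEE-TA to 0.731 between PH alone and added to PEE. For TA it was -0.0455, from -0.556 between TA added to PEE and to PEE-PH to 0.662 between TA alone and added to PEE. Array signal rose with TA over PEE but fell with TA over PEE-PH. A link to negative correlations was not tested. The median effect of PEE on NRF2 targets was 0.98 alone, 0.80 with PH, 0.90 with TA and 0.78 with PH-TA, and on cholesterol genes 0.69, 0.57, 0.65 and 0.80. On interferon genes it was -1.44, -1.39, -0.93 and -0.89, 27 of 27 down each time, and on cell cycle genes -0.39, -0.44, -0.44 and -0.09.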

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

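The tests of sums and of other splits were chosen before the data were examined. With PEE-TA 15 genes lay below the sum of the single compounds, among them C2cd4c (-1.48), Defa1 (-1.33), Alas2 (-1.23) and Il12b (-1.20), and with PH-TA 3 lay above it, Hmox1 (1.43), Gfod1 (1.16) and Lime1 (0.68). Hmox1 fell with TA alone. Blood and erythroid genes lay below the sum with PEE-PH (median -0.64) and PEE-TA (-0.55), and PPAR targets above it (0.22 and 0.17). These pairs share PEE and control arrays. Other splits of the same arrays did not exclude chance for these counts: of 100 splits 10 gave at least as many genes for PEE-TA (15 genes, highest other 2276) and 6 for PH-TA (3 genes, highest other 4259). Such splits mix strong main effects into the sum, so they say little about these counts either way. For PEE-PH and all 3 compounds limma called 0 genes, so 100 of 100 splits give at least as many by definition (highest other 3057 and 1322), which says nothing. Whether the named genes depart from the sum stays open. For PEE-TA 0 genes passed with quantile normalization. For PH-TA 0 of the 12 arrays ended the calls of Hmox1 and Gfod1. Hmox1 lost it without replicate number 2 or 3, though, and Gfod1 without each number.

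For single treatments against control the 10 splits are too few for a share under 0.05. The real split, which ranked 1, and the highest other gave 2404 and 0 genes for PEE, 1158 and 1 for PH, 403 and 0 for TA, 7914 and 1 for PEE-PH, 5626 and 0 for PEE-TA, 6521 and 1 for PH-TA and 3642 and 0 for PEE-PH-TA. Against the pairs they gave 159 and 18 for PEE-PH, 53 and 0 for PEE-TA and 2983 and 1 for PH-TA. For the average effects, with 100 splits, they gave 5962 and 2 for PEE, 6898 and 1794 for PH and 1762 and 121 for TA. These splits mix compounds too, so they say little either way.

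The tests on overall array signal were chosen after the first principal component had been seen. The spike-in test and signal relative to spike-ins replaced a first test within groups, of correlations with that component, that was too imprecise to use. Those were r = 0.0244 for spike-in signal, 0.451 for array signal (permutation p = 0.0578, adjusted 0.116, r = 0.371 without 2 arrays) and 0.419 for array signal over spike-ins (0.0234, adjusted 0.0708, r = 0.654 without 2 arrays). The last 2 go with array signal as a contributor, but did not pass. Counts for PH and TA lay along the first principal component and the overall array signal, and with that signal as a covariate the average effect of PH kept 247 of 6898 calls and that of TA 6 of 1762. Against array signal as the whole cause, the median ratio of adjusted to unadjusted fold changes was 0.749 for PH, 0.799 for TA and 0.990 for PEE, and at the lowest 0.663, 0.779 and 0.971 without a replicate number; relative to spike-ins it was 0.817, 0.910 and 1.00. Many calls ended because the median absolute fold change shrank from 0.23 to 0.16 for PH while the median SE widened from 0.0557 to 0.0946. For TA they went from 0.28 to 0.22 and from 0.0661 to 0.0897. Brighter hybridization or scanning was argued against for PH, where spike-ins differed by 0.0333 (SE 0.0442) and array signal by 0.223. It was not told apart for TA (0.0626, SE 0.0442, against 0.150). Position on the slide gave 7.66 (SE 6.75, 4 groups) against 33.5. All control and PH arrays lay in slide row 1 and all PH-TA and PEE-TA arrays in row 2. PH-TA and PEE-TA against control are thus confounded with row, and position as a partial cause stays open. RNA amount or amplification, in part or in whole, could not be excluded for the PH and TA calls. A wider shift of messenger RNA in the follicles is a hypothesis, which RNA yield per follicle would test.

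Tests of array signal and single arrays on the interferon genes were chosen before their results, and that of immune markers afterwards. Interferon response genes were lower with PEE (median -1.19). Fewer immune cells were argued against as the whole cause, because the median of macrophage and immune markers was -0.11, with -0.18, 0.05 and -0.18 by slide against -1.35, -0.66 and -1.46. Of 21 markers 4 rose, such as Lyz2 (0.32, limma, adjusted p = 0.00334) and Cd68 (0.19, 0.00599), while Ptprc was 0.07 (0.758). The 6 that fell included C1qa (-0.64), C1qc (-0.55) and Adgre1 (-0.35, 0.00681), so fewer cells of some immune types stay possible in part. With array signal in the model the interferon median was -1.15 (-1.39 to -1.04 without a replicate number), and without 1 array it ran from -1.09 (without PEE replicate 3) to -1.26. With an estimated correlation the list did not pass (0.191). Whether the same cells respond less to interferon was not tested. Interferon protein in the medium and these genes in sorted cells would test it.

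Both tests on the muscle markers were chosen before their results. Skeletal muscle markers were higher with TA (median 0.48, with 3 of 20 members past the threshold), but the list did not pass with an estimated correlation (0.31), and their mean level was as high with PEE-PH, a culture without TA (0.941, 1.32 and 1.19), as with TA alone (0.773, 0.686 and 1.11). Muscle fibres carried over unevenly at dissection may explain it: the SD between replicates of their mean level was 0.377, above 0.0707, the 95th percentile of 1000 random lists. That test told little apart, because 22 of 38 other lists were above the same value, the highest being the interferon genes at 0.380. Overall array signal was argued against, since with it in the model the median was 0.669 (0.306 to 0.880 without a replicate number). Muscle genes therefore say nothing certain about the hair follicle here.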

How the results depend on the processing

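The number of arrays, 3 per group, limited precision, and why counts moved between settings was not tested. Counts below are genes past the limma threshold, where they moved by over 1.5 times. With quantile normalization PEE-TA against the sum gave 0 and PEE-PH-TA against PEE-PH 12. Normexp background gave 5885 for PEE, 12024 for PH-TA, 12599 for the average effect of PH, 7459 for that of TA, 5290, 7 and 1 for the sums of PEE-PH, PEE-TA and all 3 compounds, and 258 and 8381 for PEE-PH-TA against PEE-PH and PH-TA. The value table of the authors gave 2 and 6 for the sums of PEE-TA and PH-TA, and 7 and 22 for PEE-PH-TA against PEE-PH and PEE-TA. Without the filter on dim probes there were 733 for PH, 165 for TA, 12710 for PEE-PH, 12649 for PH-TA, 13522 and 7131 for the average effects of PH and TA, 4628 and 0 for the sums of PEE-PH and PEE-TA, and 15, 24 and 8213 for PEE-PH-TA against PEE-PH, PEE-TA and PH-TA. A trended and robust prior gave 6 for the sum of PEE-TA, and 567 and 96 for PEE-PH-TA against PEE-PH and PEE-TA. With only the arrays of the groups compared there were 1065 for PEE, 318 for PH, 200 for TA, 3198 for PEE-TA, 4151 for PH-TA, 2209 for PEE-PH-TA, 1 and 0 for the sums of PEE-PH and PEE-TA, and 0, 0 and 522 for PEE-PH-TA against the pairs. The mean of all tested probes moved no count by over 1.5 times. Array signal as a covariate, chosen after the data were seen, gave 886 for PEE, 634 for PH, 150 for TA, 3275 for PEE-PH, 3710 for PEE-TA, 118 for PH-TA, 258 and 6 for the average effects of PH and TA, 0 for the sum of PEE-TA, and 0, 35 and 288 for PEE-PH-TA against PEE-PH, PEE-TA and PH-TA.

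Replicate numbers were not taken as pairs. After removal of group means, 44 of 84 pairs of arrays with the same number correlated above 0.1 (mean 0.101, from -0.188 to 0.351), against a mean of -0.0503 for different numbers, and 19 of 24 arrays correlated best with their own number. Each number is also 1 slide. With replicate number as a block the counts were 39 and 67 for the sums of PEE-PH and PEE-TA, and 348 and 84 for PEE-PH-TA against PEE-PH and PEE-TA. Among genes named for the size or p-value of their change 3 gained a call, all in the sum of PEE-PH, and Ccl3 lost it in the average effect of TA. Among list members named in the report Vegfc with PH gained one, and Vwf with PEE and Slc25a20 in the average effect of TA lost it.

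Leaving out each array or each replicate number gave these lowest and highest counts. For PEE they were 522 (without replicate number 2) and 1966 (without control replicate 3), for PH 0 (number 2) and 1198 (PH replicate 1), and for TA 4 (number 3) and 430 (control replicate 1). PEE-PH had 3681 (number 2) and 7545 (PEE-PH replicate 3), PEE-TA 1305 (number 2) and 5793 (PEE-TA replicate 1), PH-TA 2281 (number 2) and 6602 (PH-TA replicate 3), and PEE-PH-TA 1407 (number 2) and 3288 (PEE-PH-TA replicate 3). Average effects had 2959 (number 2) and 6041 (PEE-PH-TA replicate 3) for PEE, 2263 (number 1) and 7114 (PH-TA replicate 3) for PH, and 69 (number 3) and 2294 (PEE-TA replicate 1) for TA. The sums had 0 and 26 (control replicate 3) for PEE-PH, 0 and 49 (control replicate 3) for PEE-TA, 0 and 9 (PH-TA replicate 3) for PH-TA, and 0 and 1 for all 3. Against PEE-PH it was 0 (each number) and 602 (PEE-PH replicate 3), against PEE-TA 0 (number 3) and 284 (PEE-TA replicate 1), and against PH-TA 238 (number 2) and 3447 (PH-TA replicate 3).

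Of 39 lists camera called 17 for PEE, 15 for PH, 20 for TA, 23, 28 and 23 for PEE-PH, PEE-TA and PH-TA, 17 for PEE-PH-TA, 16, 17 and 20 for the average effects of PEE, PH and TA, 17, 17, 10 and 10 for the sums, and 15, 24 and 17 for PEE-PH-TA against PEE-PH, PEE-TA and PH-TA. In the same order an estimated correlation gave 6, 0, 0, 2, 5, 0, 3, 5, 0, 1, 2, 2, 0, 0, 0, 0 and 4. With fry there were 4 for PH, 5 for TA, 10 for the average effect of TA, 4, 2, 0 and 0 for the sums, and 3 and 1 for PEE-PH-TA against PEE-PH and PEE-TA. Without each replicate number, chosen after the data were seen, it was 11 to 18 for the sum of PEE-PH, 4 to 17 for that of all 3, and 12 to 23 and 10 to 24 for PEE-PH-TA against PEE-PH and PEE-TA.

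Among results of named genes, calls lost and gained were 99 and 0 with array signal, 38 and 0 in the value table of the authors, 10 and 0 with a trended prior, 8 and 0 with the mean of probes, 32 and 3 without the filter, 45 and 4 with normexp, 53 and 1 with only the groups compared and 31 and 0 with quantile normalization, and no other setting but normexp turned a direction. Those turned by normexp were Map7d2 with PEE-PH (-0.0751), Spon1 with PH-TA (-0.0824), in the average effect of PH Hoxc6 (-0.0890), Scgb3a1 (-0.0583), Speer6-ps1 (-0.0797), Pou2af1 (-0.0511) and Ttll9 (-0.0947), in that of TA Ascl4 (-0.0271), Serpinb13 (-0.0541) and Ffar4 (-0.0084), and against PH-TA Slc28a2 (0.0274), Gpr17 (0.122) and Slc14a1 (0.0784); Hoxc6 and Ttll9 passed in the turned direction. Without 1 array 446 of these results over all arrays lost a call and 7 gained one, and without a replicate number 274 lost one and 0 gained one. The medians of correlation between backgrounds ran from 0.338 to 0.609 for PEE, 0.0692 to 0.268 for PH and -0.0542 to 0.00360 for TA.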

Other observations

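With PEE-PH 7 of 31 hair growth factors and cytokines rose and 2 fell (7 and 2 over the list alone), with Tgfb2 (1.44 ± 0.25) and Bmp6 (1.19 ± 0.13) up and Hbegf (-0.51 ± 0.07) down, median 0.12 (limma camera, adjusted p = 0.0382, but 0.267 with an estimated correlation). With PH-TA 8 rose and 1 fell (8 and 1 over the list alone), with Tgfb2 (1.43 ± 0.25) up and the BMP inhibitor Grem1 (-0.69 ± 0.17) down, median 0.15 (0.0328, but 0.31 with an estimated correlation). With PEE-TA 6 rose and 3 fell (7 and 4 over the list alone), median 0.14 (0.047, but 0.251 with an estimated correlation). Over all genes 7914, 6521 and 5626 passed with PEE-PH, PH-TA and PEE-TA, so these members did not stand out by number. With PEE-PH-TA 11 of 31 immediate early genes rose and 1 fell (13 and 1 over the list alone), with Nr4a1 (1.00 ± 0.18) and Egr1 (0.65 ± 0.13) up and Ccn2 (-0.73 ± 0.08) down, median 0.22 (0.00875, but 0.478 with an estimated correlation).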
